A study of Rattus with 7 samples.

How the data were processed

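Live CD45+ cells, meaning blood and immune cells that carry the surface protein encoded by Ptprc, were sorted from pancreas and spleen of rats on postnatal day 1, and their transcripts were counted cell by cell. Per the labels' protocols, tissue of 5 males and 5 females was pooled within each sex, sorting yielded 28000 to 63000 cells from a pancreas sample and 100000 from a spleen sample, and libraries were made with the 10x Genomics Chromium 3' version 2 chemistry and sequenced on an Illumina HiSeq2500. The kit captures the 3' end of polyadenylated RNA and tags each captured molecule with a unique molecular identifier (UMI), so amplification copies are not counted again. Per the file headers, the authors made the deposited counts with Cell Ranger 6.1.2, and per the submitters' processing notes the genome build was mRatBN7.2 and Seurat 5.0 was used at a step the notes do not name. The gene annotation is not given in the sources used here. The deposited values are whole UMI counts per gene and barcode, not normalized, for 23096 genes in 7 libraries, and 391 gene entries share a symbol with another entry and were kept apart by their identifiers.

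Each library title holds the letter C or I, the letter F or M and the tissue. The letters F and M were taken as female and male, and C and I are kept as letters. The series title concerns intrauterine growth restriction, but the labels used here do not spell these letters out. The groups were C pancreas (1 F and 1 M library), I pancreas (1 F and 1 M library), C spleen (1 F and 1 M library) and I spleen (1 M library). An F library of I spleen was not analysed here. Every library is a pool of animals, and the paired members of a group are of opposite sex, so each p-value measures a spread between pools that includes the difference between the sexes. The lone I spleen library was assumed to vary like the libraries of the other groups. In clusters 1 and 10, fitted on the spleen libraries alone, the spread came from the C F and C M pair only, with 1 residual degree of freedom.

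Barcodes with at least 200 detected genes and under 10% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet as built into scanpy 1.11.5. Its automatic threshold marked 1 barcode in all, so the highest scores were removed instead, at an expected rate of 0.8% per 1000 cells, a rule set after the scores were seen. Counts were scaled to 1000 UMIs per cell and logged, 2000 variable genes were chosen within libraries, and 30 principal components with 15 neighbours gave a graph for Leiden clustering at resolution 1 with leidenalg 0.10.2 and igraph 0.11.9. Sex check genes, mitochondrial and ribosomal protein genes and the acinar, endocrine and erythroid marker genes were left out of the variable genes, and libraries were not integrated. A cluster was called "X-like" where at least 3 markers of 1 of the 22 lists were detected in 5% of its cells at a log2 ratio of at least 1 over the other clusters and the list led the next by a factor of 1.25 or by 3 genes among the top 10. This naming rule was set after the clusters were seen, and it left clusters 1, 6, 7, 10, 16 and 17 unnamed. Marker lists were fixed before. Most of the genes named in the text were among the variable genes used for clustering.

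UMIs were summed per library and class, and the sums were tested with edgeR 4.0.16 (TMM scaling, filterByExpr by group, quasi-likelihood test, Benjamini-Hochberg adjustment within a class, threshold 0.05) in R 4.3.3. Classes with 20 cells in each of the 7 libraries were fitted over all libraries with 1 mean per group. Classes reaching 20 cells in 1 tissue only were fitted over the libraries of that tissue, and at most 6 classes per contrast were tested. The contrasts were I against C in pancreas, I against C in spleen, pancreas against spleen in C, and the difference of the I effect between the organs. Standard errors of log2 fold changes were derived from the F statistic. Group levels of a gene in a class are given as CPM, as mean ± SD over libraries. For these, the UMIs of the genes kept by filterByExpr in that class were scaled by TMM to a common total per library. Haemoglobin levels, summed defensin levels and levels over all kept cells were instead scaled to all UMIs of the summed cells, without TMM. Group levels in a class are therefore not on the same CPM scale as these. Class shares were tested with the same package on cell numbers (1 dispersion, library size equal to kept cells, 20 classes per contrast) and carry exact Clopper-Pearson 95% intervals. Intervals and limits from counts cover counting error only. A test of the sex letter used the sums over all kept cells with the group as a term.

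The 14 gene lists were type 2 immunity, inflammatory cytokines and NF-kB targets, interferon response, MHC class II presentation, MHC class I presentation, resident macrophage genes, cell cycle, immediate early and heat shock genes, hypoxia and glycolysis, oxidative phosphorylation, glucocorticoid response, oxidative stress response, neutrophil granule genes, and lymphocyte effector and T helper genes. A list with at least 3 tested members was tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a class, in 127 tests over both I against C contrasts. Beside each count of members past the threshold over all genes, the count adjusted over the list alone is given.

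Genes are named by a fixed rule. Among genes past the threshold whose groups did not overlap, the rule took the 5 with the largest and the 5 with the smallest log2 fold change at an average log2 CPM of at least 5, up to 30 per contrast, class by class. Where none passed, the 2 genes of smallest p in each direction were named, and for each list called by camera up to 4 members of smallest p. Marker genes of exocrine, endocrine and red cells and mitochondrial and immunoglobulin genes were not named singly, and genes without a symbol were not named. Of the genes the rule names, 1 is not reported here. A gene at 0 UMIs in every library of a group is given a bound against 3 counts over the group. The groups, tests, lists, naming rule for genes and most alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0, no filter on low counts, the sex letter as a block, the libraries of 1 tissue alone, a stricter cell filter (500 genes, 5% mitochondrial UMIs), doublets kept, each library left out, Leiden resolutions 0.5 and 2, TMM over classes, an estimated correlation and fry. No gene minimum, single clusters of a class and sums without the highest cell of each gene were added after the data were seen.

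The count test was tested on simulated data drawn from each gene's mean over all libraries and the spread fitted by edgeR, with 200 genes changed in each of 10 simulations. In macrophage-like cells of the pancreas, 42.4% of genes changed 2-fold and 78.7% of those changed 4-fold were recovered over 5429 genes, and 3.4% of the calls were false. For B cell-like cells of the spleen (1939 genes) the values were 74.0%, 88.2% and 6.8%. For macrophage-like cells between the tissues (5429 genes) they were 11.1%, 37.6% and 4.1%. With no gene changed, a run of each case gave 0, 1 and 0 calls, in the same order. The simulated counts followed the model of the test, so they do not cover a shift of a whole library or of the make-up of a class. Both libraries of each group differed by more than counting noise, with a chi-square per degree of freedom of 3.58 in C pancreas, 4.84 in I pancreas and 15.8 in C spleen. Other packages were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.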

Results

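The data are single-cell RNA counts of live CD45+ cells sorted from the pancreas and spleen of rats at postnatal day 1. The series title asks how intrauterine growth restriction affects the developing immune system of the pancreas. The libraries carry the letters I or C, and both sexes were collected, each as a pool of animals. There were 4 pancreas libraries (C and I, F and M) and 3 spleen libraries (C of both sexes and I of the M pool). In pancreas, the C F library held 3018817 UMIs over 4294 barcodes, the C M library 2362417 over 3944, the I F library 1757725 over 2759 and the I M library 3657960 over 5553. In spleen, the C F library held 6985613 UMIs over 5106 barcodes, the C M library 11380724 over 6092 and the I M library 5337626 over 5725. After filtering, 3371, 2780, 1829 and 4241 cells of the pancreas libraries (same order) and 4773, 5718 and 5228 of the spleen libraries were kept. Median depths were 586 to 647 UMIs per cell in pancreas and 947, 1173 and 606 UMIs in the spleen libraries. The filters removed 32.1% of the barcodes of the I F pancreas library and 18.8%, 27.1% and 20.2% of those of the C F, C M and I M pancreas libraries, against 1.13% to 3.28% in spleen. Ptprc, which encodes CD45, stood at 175 to 201 CPM in the pancreas libraries and 239 to 275 CPM in the spleen libraries.

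The letters F and M were checked first. The Y-linked genes Kdm5d, Uty and Eif2s3y, which are carried by males, were at 0 to 1.9 CPM in the F libraries and at 11.2 to 97.7 CPM in the M libraries. The libraries thus matched their letters. Over all kept cells, 15 of 11753 genes followed the sex letter with the group as a term (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), 8 higher and 7 lower in F. Kdm6a, an X-linked histone demethylase gene, was higher in F (log2 fold change 0.65 ± 0.11 SE, adjusted p = 0.0428). The count moved with the libraries used, to 227 without the C F pancreas library, 224 without the C M, 116 without the I F and 114 without the I M pancreas library, and to 5 and 6 without the C F and C M spleen libraries.

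Clustering gave 25 clusters, of which 19 were named by their markers. In pancreas the sorted cells were mostly myeloid, with monocyte-like cells at 18.2% to 40.4%, macrophage-like cells at 14.2% to 26.7% and cluster 6, led by Slpi, Ccl24, Prg4, Cxcl1, Pf4 and Fn1, at 7.80% to 17.1% of cells. In spleen, B cell-like cells made 30.3% and 38.8% of the C libraries and 60.1% of the I library. Of the unnamed clusters, cluster 1 was led by the B lineage genes Vpreb3 and Bach2, clusters 7 and 10 by the proliferation genes Pclaf and Top2a, and Cenpf and Ube2c, cluster 16 by Mal, G0s2 and Nr4a1, and cluster 17 by the collagen genes Col3a1 and Col1a1. The unnamed clusters 1, 7, 10, 16 and 17 together with cluster 6 were kept apart by a threshold set after the data were seen. Of 10 B cell markers, 9 were raised in cluster 1 and 7 in each of clusters 7 and 10. The B cell-like share therefore leaves out part of the B lineage. Cluster 1 made up 14.7% and 25.5% of the C F and C M spleen libraries and 12.3% of the I spleen library. Cluster 16 held 1.04% to 2.19% of each library, cluster 7 held 1.27% to 2.95% in pancreas and 3.54% to 12.3% in spleen, and cluster 10 held 0.613% to 1.37% in pancreas and 2.30% to 6.39% in spleen.

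**Figure D1:**
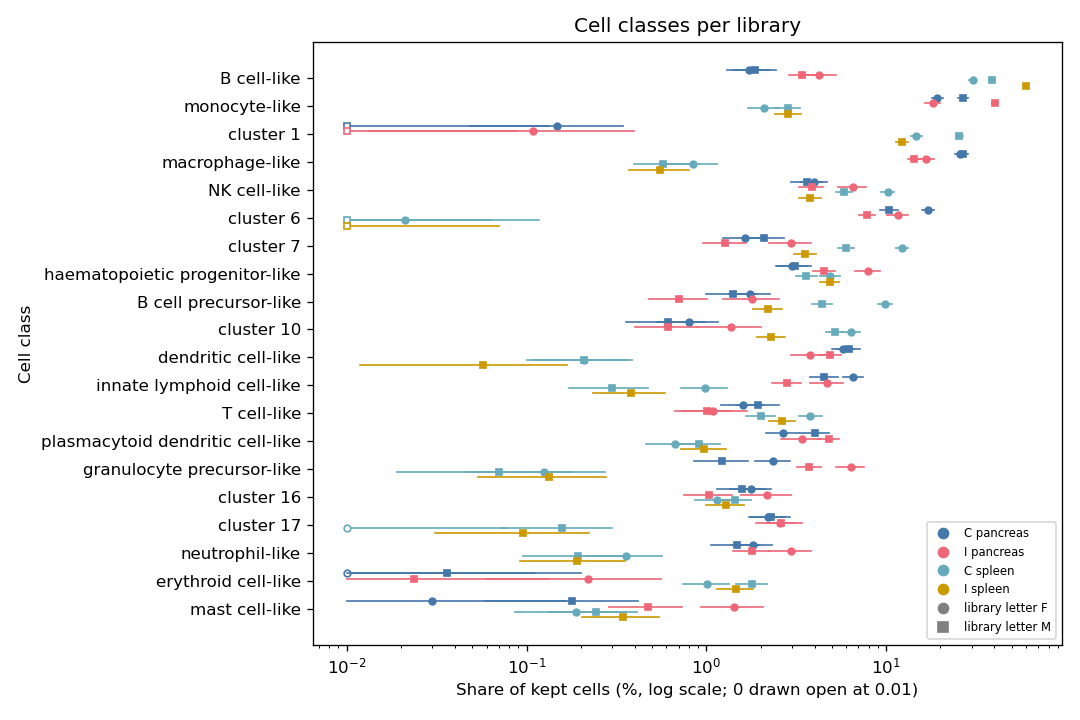
Share of kept cells (percent, log axis) of each class in the 7 libraries, with 1 point per library coloured by group, circles for F and squares for M, and exact 95% intervals of counting error as bars. Shares of 0 are drawn as open points at the left edge. Mast cell-like cells were at 0.0297% and 0.180% in the C pancreas libraries and at 1.42% and 0.472% in the I pancreas libraries.

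Mast cell-like cells, named after the tissue cells that release histamine and proteases, made up 0.947% ± 0.672 (SD, n = 2) of cells in I pancreas and 0.105% ± 0.106 (n = 2) in C pancreas, an 8.73-fold difference (log2 3.12 ± 0.82 SE, edgeR's quasi-likelihood test on cell numbers, Benjamini-Hochberg adjusted p = 0.00703). In this cluster 6 of 10 mast cell markers were raised, and 4 of 9 of the basophil list, which shares members with it. Prss34 of the basophil list and Prg2 and Epx of the eosinophil list were among its leading genes, so it may mix these cell types. The difference rested on 26 and 20 cells in the I F and I M libraries (exact 95% intervals 0.931% to 2.08% and 0.288% to 0.727%) against 1 and 5 cells in the C F and C M libraries (0.0008% to 0.165% and 0.0584% to 0.419%). Granulocyte precursor-like cells, the cells in which granule proteins are made, were at 5.03% ± 1.85 (SD, n = 2) in I and 1.78% ± 0.792 in C pancreas (2.79-fold, log2 1.48 ± 0.58, adjusted p = 0.131). B cell-like cells were at 3.81% ± 0.559 against 1.80% ± 0.106 (adjusted p = 0.383), and haematopoietic progenitor-like cells at 6.20% ± 2.37 against 3.04% ± 0.069 (adjusted p = 0.383). Monocyte-like cells were at 29.3% ± 15.8 against 23.0% ± 5.21 (adjusted p = 0.652). Of 20 classes, 1 passed in pancreas. At the lower and higher clustering resolution the mast cell-like cluster kept its 93 cells and its cell number in each library. Only the other classes, which share its dispersion and adjustment, changed there. The mast cell-like call ended with the sex letter as a block (adjusted p = 0.117) and with the stricter cell filter (0.641). At the lower and higher resolution it ended as well (0.121 and 0.155). It also ended without the C F pancreas library (log2 2.31, 0.383), the I F pancreas library (log2 2.22, 0.402), the C F spleen library (0.225) or the C M spleen library (0.225). With 1 library left out in turn the mast cell-like log2 ratio ranged from 2.22 to 4.79. Granulocyte precursor-like cells passed with the block (0.0473). Macrophage-like (adjusted p = 0.548), cluster 6 (0.652) and dendritic cell-like (0.652) shares were tested among the 20 classes and did not pass. Genes that lead these clusters differed between the groups, so their shares describe the clusters and are not set against each other as cell types. In spleen, 0 of 20 classes passed in the same test (1 at an unadjusted p under 0.05; no other tool was run for shares). The B cell-like share of 60.1% in the I library stood beside 34.5% ± 6.02 (SD, n = 2) in C (adjusted p = 0.732) and the B cell precursor-like share of 2.20% beside 7.12% ± 3.83 (adjusted p = 0.457).

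Macrophage-like cells of I pancreas held more defensin transcripts and fewer transcripts of Apoe and Cd209f than those of C pancreas. The make-up of the class differed by group, since cluster 18, led by Fcna, Hmox1 and Spic, held 42 of 868 and 40 of 742 cells in the C F and C M and 47 of 303 and 54 of 604 in the I F and I M libraries, and cluster 3 the rest. Spp1, which encodes the secreted protein osteopontin, rose from 20.6 ± 18.2 to 79.8 ± 0.283 CPM (SD, n = 2 each; log2 2.05 ± 0.38 SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3e-05). Its UMIs came from 8 of 303 and 27 of 604 cells in the I F and I M libraries, with 7 of the 19 UMIs of the I F library in 1 cell, and from 6 of 868 and 18 of 742 cells in the C F and C M libraries. Spp1 leads the monocyte-like cluster 2, and it was seen in 6.33% and 15.8% of monocyte-like cells (median 577 and 451 UMIs) of the I F and I M libraries. In NK cell-like cells, which should lack it, Spp1 was seen in 0 of 119 and 0 of 163 cells of these libraries (median 664 and 654 UMIs). That allows a share of up to 2.52% and 1.84%, against 2.64% and 4.47% of the macrophage-like cells (median 781 and 872 UMIs). In the I M library other classes were at 6.67% (2 of 30 B cell precursor-like cells), 5.44% (cluster 6), 4.55% (cluster 17), 2.33% (T cell-like) and 1.68% (innate lymphoid cell-like). Dendritic, B cell-like and plasmacytoid dendritic cell-like cells were at 0.97%, 0.69% and 0.49% there, and clusters 7 and 16 at 0%. The macrophage-like share of this library lay above most of these shares. It lay below those of B cell precursor-like cells and clusters 6 and 17, so whether it is above background is not settled. The defensin genes Np4 and Defa5, which encode antimicrobial peptides of granules, rose by log2 1.98 ± 0.25 and 2.03 ± 0.36. Apoe, which encodes a lipid carrier, fell from 1424 ± 63.1 to 780 ± 28.4 CPM (log2 -0.87 ± 0.16, adjusted p = 2.24e-05), and Cd209f, a lectin receptor gene, from 207 ± 42.2 to 98.0 ± 33.0 CPM (log2 -1.21 ± 0.22, adjusted p = 2.04e-05). Ikbip had log2 1.70 ± 0.21 and Mtmr12 log2 -1.14 ± 0.28. Of 5429 genes, 34 passed, 25 higher and 9 lower in I. Np4 and Apoe kept their calls without any 1 library and with DESeq2, which called 4 genes. Spp1 was lost without the C F (log2 1.23, adjusted p = 0.999), I F (0.067) and I M (0.275) pancreas libraries, and Defa5 without the C M (0.0665) and I F (0.146). Cd209f was lost without the C F (log2 -0.96, 0.234) and I M (log2 -0.80, 0.618) and Ikbip without the I M (log2 0.46, 0.962). Mtmr12 was lost without the C F (0.0601), C M (0.723), I F (0.15) and I M (0.628). Without a library the count was 13 (C F), 15 (C M), 16 (I F) and 14 (I M) in pancreas and 20 for each spleen library. It was 14 with the pancreas libraries alone and 22 with the sex block. In cluster 3 alone it was 23, with Mtmr12 (0.0826) and Colec12 (0.142) lost, and in cluster 18 alone 0. Defensin copies are alike in sequence, as are those of the RT1 family and pseudogenes of Eef1a1, so counting could split their reads. In the same libraries the summed defensins of the granulocyte precursor-like cells were at 157342 to 218835 CPM. Over all cells the defensins were at 7135 and 4087 CPM in C and 23955 and 17798 CPM in I. Haemoglobin genes, which mark red cells, moved with the group too, at 29.2 and 99.6 CPM in the C and 3198 and 2108 CPM in the I macrophage-like cells.

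**Figure D2:**
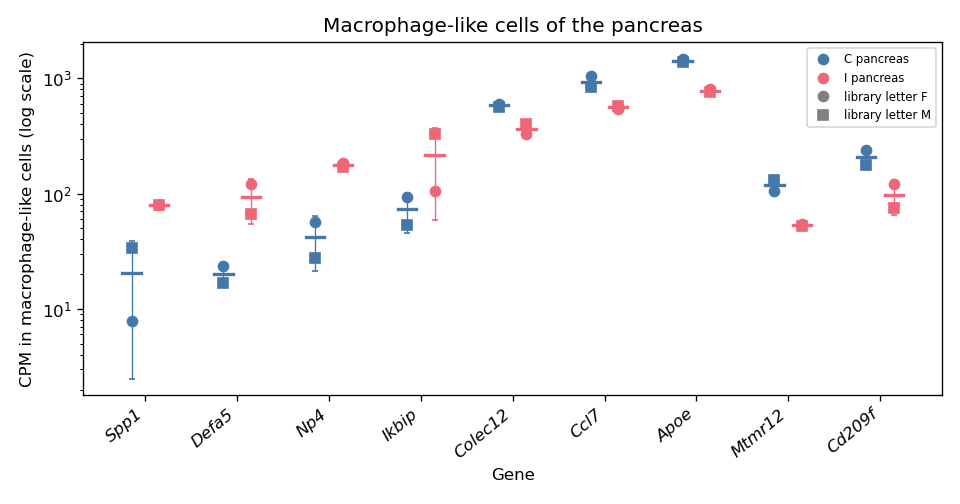
Levels (CPM of summed UMIs, log axis) of 9 named genes in macrophage-like cells of the pancreas, with 1 point per library (circles F, squares M), the group mean as a line and the SD as a bar, for C and I. Both I libraries lay above both C libraries for Spp1, Defa5, Np4 and Ikbip and below them for the other 5.

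By gene list, the resident macrophage genes of these macrophage-like cells were lower in I (camera, adjusted p = 1.26e-06, and adjusted p = 0.359 with an estimated correlation), with 2 of 20 members lower over all genes and 5 adjusted over the list alone. The list of inflammatory cytokines and NF-kB targets was lower (adjusted p = 0.00151, and 0.364 with an estimated correlation), with 3 of 21 lower and 7 adjusted over the list alone. Its members Ccl2 (log2 -0.65 ± 0.16, adjusted p = 0.00846) and Ccl4 (-0.64, 0.0439), genes of chemokines that attract monocytes and other leukocytes, fell, and the third past the threshold was Ccl7 (-0.74 ± 0.16, 0.000745). Ccl2 (0.225), Ccl4 (0.47) and S100a9 of the granule list (0.385) were lost in cluster 3 alone. Ccl2 was lost without the C F (0.999) and I M (0.683) pancreas and the C F (0.06) and C M (0.061) spleen libraries. Ccl7 was lost without the C F (0.583) and I F (0.0774) pancreas libraries and Ccl4 with the sex block (0.31) and without each library in turn (0.058 to 0.999). MHC class II genes, which present antigens, were lower (adjusted p = 0.000193, and 0.365 with an estimated correlation), with 1 of 9 lower and 3 adjusted over the list alone. The member past the threshold, RT1-Db1 (log2 -0.92 ± 0.23, adjusted p = 0.0172), stood at -0.19 without the I M pancreas library (0.986) and was lost with the sex block (0.306) and without the C F pancreas library (0.999) or any 1 spleen library (0.11 to 0.264). Type 2 immunity was lower (adjusted p = 0.0479, and 0.364 with an estimated correlation) with 0 of 5 past over all genes in edgeR and 2 lower adjusted over the list alone. Its member Il10 had log2 -1.02 ± 0.39 (adjusted p = 0.436). Neutrophil granule genes were higher (adjusted p = 0.000693, and 0.359 with an estimated correlation), with 1 of 8 higher, S100a9 (log2 0.61, adjusted p = 0.0178), and 4 higher and 1 lower adjusted over the list alone. S100a9 was lost without the C M (1), I F (0.396) and I M (0.263) pancreas and each spleen library (0.073 to 0.21). The MHC class II call ended without the C F (0.0753) and I M (0.623) pancreas libraries, the granule call without the C M (0.366) and I M (0.0782), and the type 2 call without the C F (0.0948), C M (0.719), I F (0.14) and I M (0.105). Colec12 (log2 -0.66) and Ccl7 lead the class, so their fall in I cannot be told apart from which cells the class took in. In cluster 3 alone, which both lead, Ccl7 still passed. Selenop, Stab1, Mrc1, Cd163, F13a1 and Maf of the resident macrophage list lead cluster 3 as well. The call of that list therefore cannot be told apart from the make-up of the class.

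In cluster 6 of the pancreas, the defensin genes Np4 (229 ± 29.7 against 48.0 ± 29.0 CPM, SD, n = 2 each; log2 2.04 ± 0.34), Defa5 (2.42 ± 0.50) and RatNP-3b (1.45 ± 0.37) rose. So did Jund, a gene of the AP-1 transcription factor (2165 ± 195 against 1118 ± 70.9 CPM, log2 0.95 ± 0.16, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.02e-06), and Vcan, a matrix proteoglycan gene (1.5 ± 0.34). RT1-CE16, an MHC class I gene, fell from 491 ± 24.8 to 162 ± 73.0 CPM (log2 -1.5 ± 0.26, adjusted p = 5.43e-06). Cd163, a haemoglobin scavenger receptor gene (-1.01 ± 0.27), F13a1 (-1.18 ± 0.32), Trem2, a lipid receptor gene (-1.36 ± 0.37), and Ifi27, an interferon-induced gene (-1.18 ± 0.28), fell too. Resident macrophage genes were lower as a list (camera adjusted p = 2.34e-07, and 0.291 with an estimated correlation), with 6 of 16 lower and 8 adjusted over the list alone, among them C1qc (-0.59), Selenop (-0.85) and Pf4 (-0.60), of which Pf4 leads the cluster. Ccl24, C1qa and C1qb of this list lead the cluster as well. MHC class II genes were lower too (adjusted p = 0.0203, and 0.666 with an estimated correlation), with 0 of 5 past in either count and RT1-DMa at log2 -0.51 (adjusted p = 0.483). This call ended without the C F (0.672) and I M (0.0744) libraries. Haemoglobin genes were at 20.9 and 29.6 CPM in the C and 222 and 74.5 CPM in the I libraries of this cluster. In all, 23 of 2458 genes passed, 9 higher and 14 lower. The count was 3 with doublets kept, 3 without the highest cell of each gene, 6 in DESeq2, 10 without the C F, 8 without the C M and 43 without the I M pancreas library. Np4 and RT1-CE16 kept their calls without any 1 library. With the sex block Trem2 (0.0638), Pf4 (0.173) and C1qc (0.157) were lost. The calls lost without the C F library were Jund (0.0839), Vcan (0.308), RatNP-3b (0.108), Trem2 (0.308), Pf4 (0.859), C1qc (0.859) and Ifi27 (log2 -0.69, 0.995). Those lost without the C M library were RatNP-3b (0.197), F13a1 (0.445), Trem2 (0.17), Pf4 (0.523), C1qc (0.524), Cd163 (0.731) and Selenop (0.731). Those lost without the I F library were Defa5 (0.364), RatNP-3b (0.253), F13a1 (0.137), Trem2 (0.364), Cd163 (0.481) and Selenop (log2 -0.57, 0.507). Those lost without the I M library were F13a1 (0.234) and Ifi27 (log2 -0.62, 0.666).

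In dendritic cell-like cells of I pancreas, Ccl5, a gene of a chemokine that attracts T cells, fell from 743 ± 78.8 to 183 ± 109 CPM (SD, n = 2 each; log2 -2.32 ± 0.32 SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.07e-10), and Vps13c fell by 2.01 ± 0.42 on the log2 scale. The Ccl5 transcripts came from few cells, 82 UMIs in 13 of 195 and 78 in 11 of 172 cells of the C F and C M libraries, and 11 in 4 of 69 and 14 in 9 of 207 cells of the I F and I M libraries, with 8 of the 11 in 1 cell. Ccl5 leads the NK cell-like cluster, where it was seen in 76.2% to 85.9% of cells (median 534 to 664 UMIs), against 1.38% to 3.90% of B cell-like cells (541.5 to 581.5 UMIs) and 4.35% to 6.67% of dendritic cell-like cells (605 to 662 UMIs). In the C F and C M libraries B cell precursor-like cells were at 5.08% and 5.13% and plasmacytoid dendritic cell-like cells at 6.67% and 0%. T cell-like cells were at 0% and 3.70% in C and 5.0% and 13.95% in I F and I M, and macrophage-like cells at 1.35% to 3.63%. Some other classes thus reached the dendritic cell-like share. Haemoglobin genes were at 247 and 151 CPM in the C and 512 and 344 CPM in the I dendritic cell-like cells. Np4 rose from 34.4 ± 34.3 to 311 ± 95.7 CPM (log2 2.91 ± 0.50). Fscn1, an actin-bundling gene of mature dendritic cells (2.20 ± 0.59, adjusted p = 0.0499), and Tubb5, a tubulin gene (0.80 ± 0.19), rose too. RT1-Bb had log2 -0.94 and leads the class. These were the 6 of 1591 genes that passed (1 in DESeq2, 3 without the C F, 1 without the C M and 12 without the I F pancreas library). Ccl5 was lost without the I M library (log2 -1.49, 0.194), and Np4 without the C M (0.0645). Vps13c was lost without the C F (0.0572), C M (0.0839) and I M (0.783) and Fscn1 without the C F (0.0572) and C M (0.501). With the sex block Fscn1 (0.217) and Tubb5 (0.0705) were lost. Tubb5 was lost without the C F (0.443), C M (0.506) and I F (0.159), and RT1-Bb without the C F (0.195), C M (0.364) and I M (log2 -0.24, 0.921). Lower lists included the inflammatory list (camera adjusted p = 3.24e-07, 1 of 7 lower, 3 adjusted over the list alone) and MHC class II (0.00137, 1 of 11 lower, 2 adjusted over the list alone). Resident macrophage genes (0.000309, 0 of 6 past, 2 lower adjusted over the list alone) and the glucocorticoid response (0.0446, 0 of 3 past, 1 lower adjusted over the list alone) were lower too. The first 3 had adjusted p = 0.321 with an estimated correlation and the last 0.373. RT1-Ba, RT1-Bb, RT1-Da, RT1-Db1 and Cd74 of the MHC class II list lead the class. The call of that list thus cannot be told apart from which cells the class took in. The MHC class II call ended without the C F (0.0771) and I M (0.104) libraries, the resident macrophage call without the I M (0.0557), and the glucocorticoid call without the C F (0.244), I F (0.188) and I M (0.0623). In innate lymphoid cell-like cells, Ccl5 (log2 1.96 ± 0.33), Np4 (2.15 ± 0.57) and Tubb5 (0.65 ± 0.16) rose, the 3 of 762 genes that passed. The class was named by 3 of 14 markers, Rora, Gata3 and Il23r. At the lower clustering resolution no cluster took this name, and the T cell-like cluster held 1234 cells against 605. The name thus depends on the resolution. The Ccl5 transcripts of the I F and I M libraries came from 8 and 6 cells, with 21 of 45 and 16 of 25 UMIs from 1 cell. In these libraries 5.0% and 13.95% of T cell-like cells, 4.26% and 3.64% of cluster 17 and 3.90% and 1.38% of B cell-like cells held Ccl5. The shares were 9.30% and 5.04% of innate lymphoid cell-like cells. Haemoglobin genes were at 18.0 and 32.3 CPM in the C and 200 and 53.4 CPM in the I libraries of this class. The count was 0 in DESeq2, with the sex block, with doublets kept and without the C M library, where the adjusted p was 0.998 for each gene. Ccl5 was also lost without the C F (0.214) and I F (log2 1.04, 0.487), Np4 without the C F (0.574), I F (0.487) and I M (0.381), and Tubb5 without the I M (0.398).

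In monocyte-like cells of the pancreas, Defa5 rose from 13.2 ± 8.63 to 84.7 ± 1.27 CPM (SD, n = 2 each; log2 2.66 ± 0.46 SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0414). It was lost without the C F (0.156) and C M (1) pancreas libraries, without the I M spleen library (0.0761) and in DESeq2. It was 1 of 2 genes past the threshold among 5500, and the other has no symbol. The count was 20 with the sex block, 0 without the C M pancreas library, 0 without the I M spleen library, 1 without the C F, 14 without the I F and 75 without the I M pancreas library. The I M library holds most of its monocyte-like cells in cluster 2 (1380 against 335 in cluster 8), while the I F library holds 145 in cluster 2 and 187 in cluster 8. Haemoglobin genes were at 35.3 and 62.7 CPM in the C and 159 and 154 CPM in the I monocyte-like cells. Neutrophil granule genes were higher as a list (camera adjusted p = 7.77e-08, and 0.36 with an estimated correlation), all 11 members above 0 with 0 past in either count. Mpo, the myeloperoxidase gene, was at log2 1.85 ± 0.58 (adjusted p = 0.928). Oxidative phosphorylation was higher (adjusted p = 0.0152, and 0.593 with an estimated correlation), with 43 of 59 members above 0, 0 past in either count and Cycs at log2 0.41. Resident macrophage genes (2.31e-06, 0 of 17 past in either count) and the inflammatory list (5.67e-05, 0 of 21 past, 2 lower adjusted over the list alone) were lower. So were MHC class II (0.000304, 0 of 10 past, 4 lower adjusted over the list alone) and immediate early and heat shock genes (0.00522, 0 of 23 past in either count). Each of these 4 had adjusted p = 0.36 with an estimated correlation. Without the I F library the calls of resident macrophage genes (0.432), immediate early genes (0.142) and oxidative phosphorylation (0.511) ended. The last also ended without the C M library (0.149), and that of MHC class II without the I M library (0.0501). Among their members, Ccl2 had log2 -0.83 ± 0.25 (adjusted p = 0.836, 0.0253 with the sex block, and -1.48 with 1.36e-06 without the I M library) and RT1-Ba -1.58 ± 0.41 (adjusted p = 0.41). In this class 187 genes had an unadjusted p under 0.05 and DESeq2 called 0 genes. In haematopoietic progenitor-like cells 1 of 3989 genes passed, Prg2, the gene of eosinophil major basic protein, with 127 UMIs in 4 cells of the I F and 413 in 10 cells of the I M library against 0 and 1 UMI in C. Prg2 was chosen after its values were seen, and 113 and 134 of its UMIs came from 1 cell in each I library. Prg2 leads the mast cell-like cluster, which held 26 and 20 cells in the I and 1 and 5 cells in the C pancreas libraries. The count was 5 with the sex block, 3 and 2 without the I F and I M pancreas libraries and 6 without either C spleen library. Lists called there were resident macrophage genes (lower, 0.00143, 7 members), immediate early and heat shock genes (lower, 0.0254, 17 members), oxidative phosphorylation (higher, 0.0302, 58 members) and neutrophil granule genes (higher, 0.0302, 8 members). They had 0 members past over all genes or adjusted over the list alone, and adjusted p = 0.468 with an estimated correlation. Mpo had log2 0.51 and Jund 0.61 there. Without the C F pancreas library the first 3 of these calls ended (0.82, 0.82 and 0.426). The immediate early call also ended without the I F (0.137) and I M (0.0815) pancreas and the I M spleen library (0.155). The phosphorylation call ended without each spleen library (0.0593 to 0.191). The granule call ended without each spleen library (0.0593 to 0.464) and the C M (0.163) and I M (0.2) pancreas libraries.

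**Figure D3:**
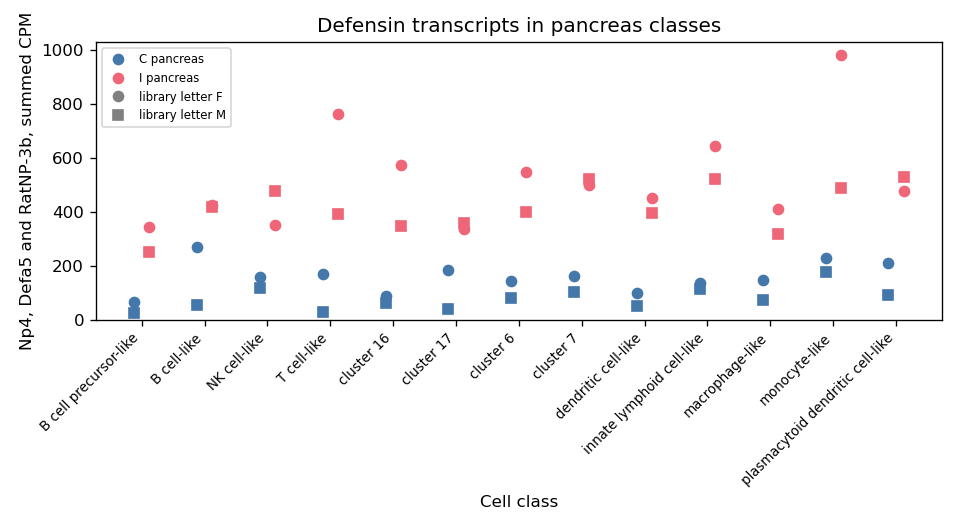
Summed defensin transcripts (Np4, Defa5 and RatNP-3b, CPM) in 13 classes of the pancreas, with 1 point per library (circles F, squares M), for C and I. In macrophage-like cells the I libraries were at 412 and 319 CPM and the C libraries at 146 and 72.2 CPM.

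In B cell-like cells of the I spleen library, Crebbp, a histone acetyltransferase gene, stood at 160 CPM against 63.4 ± 1.27 (SD, n = 2) in C (log2 1.33 ± 0.23 SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0128) and Jund at 522 against 214 ± 81.7 CPM (log2 1.32 ± 0.24, adjusted p = 0.0182). RT1-CE16 was at 87.2 against 259 ± 12.3 CPM (log2 -1.57 ± 0.21, adjusted p = 0.0016). The MHC class II gene RT1-Bb was at 90.9 against 247 ± 43.9 CPM (log2 -1.45 ± 0.22, adjusted p = 0.00517), and Etfb had log2 -1.07 (adjusted p = 0.0337). Of 1939 genes, 6 passed, 3 in each direction. Without the C M spleen library the count was 0, and Crebbp (0.485), Jund (0.417), RT1-CE16 (0.33), RT1-Bb (0.485) and Etfb (0.997) were lost. Without the C F spleen library it was 12, with Crebbp (0.241) and Etfb (0.19) lost, and without the I F pancreas library 11, with Jund (0.0562) and Etfb (0.077) lost. Without the C F, C M and I M pancreas libraries it was 49, 47 and 31, and with the spleen libraries alone 95. MHC class II genes were lower (camera adjusted p = 0.00368, and 0.334 with an estimated correlation), with 1 of 6 lower in either count. Immediate early and heat shock genes (0.0445, 14 members), hypoxia and glycolysis (0.0445, 0 of 9 past, 2 lower adjusted over the list alone) and the oxidative stress response (0.0117, 0 of 11 past, 1 lower adjusted over the list alone) were lower too. Each had adjusted p = 0.287 with an estimated correlation. In the immediate early list the 1 member past over all genes, Jund, was higher, with 1 higher and 2 lower adjusted over the list alone. Fosb had log2 -1.24 (adjusted p = 0.265). Ldha had log2 -0.60 and Gstp1 -0.79. The MHC class II call ended without each pancreas library (0.772 to 0.837). Without the C F spleen library the immediate early (0.504), glycolysis (0.238) and oxidative stress (0.225) calls ended, without the C M spleen library the immediate early (0.441) and glycolysis (0.181) calls, and without the I M pancreas library the glycolysis call (0.0542). With the sex block Crebbp (0.106) and the immediate early (0.264) and glycolysis (0.0918) calls ended. Of these cells, 2432 lie in cluster 0 and 708 in cluster 4 in I, against 1064 and 381 in the C F and 1746 and 472 in the C M library, and RT1-Bb had log2 -1.5 (0.000148) in cluster 0 and -1.61 (0.0695) in cluster 4 alone. At the higher clustering resolution the make-up of the B cells differed by group. There, 1 cluster led by Ltb and Cd74 held 1328 I cells against 323 and 88 in the C F and C M libraries, and 1 led by Bank1, Cd74 and RT1-Bb held 365 against 393 and 894. Haemoglobin genes were at 2374 CPM in the I and 4171 and 3526 CPM in the C B cell-like cells. The I group is 1 M library here and C holds an F and an M library, so condition, library and in part sex cannot be separated by the design.

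Crebbp rose and RT1-CE16 fell in cluster 1 and NK cell-like cells of the spleen as well, while RT1-CE16 had log2 0.69 in B cell precursor-like cells (0.531) and -0.76 in cluster 10 (0.745). In cluster 1, Crebbp stood at 230 against 78.9 CPM in C (log2 1.59 ± 0.28 SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.84e-05). Hvcn1, a proton channel gene, Ccdc71, Marf1 and Lcp1, an actin-bundling gene, had log2 1.53, 1.42, 1.17 and 1.16. RT1-CE16 (-1.57), the elongation factor gene Eef1a1 (-1.22), Dpp4 (-1.53) and Rpia (-2.02) were lower. This fit held the spleen libraries alone, with 1 residual degree of freedom from the C F and C M pair, as did that of cluster 10. In cluster 1, 20 of 5231 genes passed (1 in DESeq2, 0 with doublets kept, 9 without the filter on low counts). A sex block could not be fitted there, and the Y-linked gene Uty was among the 20 (log2 1.08, adjusted p = 0.0331), at 212 CPM in I and 0 and 159 CPM in the C F and C M libraries. Haemoglobin genes were at 11315 CPM in I and 9817 and 5842 CPM in C, though Hba-a3 was lower (log2 -3.02). MHC class II genes were higher (camera adjusted p = 8.05e-05, and 0.9 with an estimated correlation), with all 8 members above 0. Past the threshold were 1 higher, RT1-Db1 (log2 1.03), and 3 adjusted over the list alone. In NK cell-like cells 13 of 1938 genes passed. The count was 25 with the sex block, 0 in DESeq2, 0 without the C F and C M pancreas libraries each, 1 without the I F or I M pancreas library, and 28 and 8 without the C F and C M spleen libraries. Crebbp (log2 1.68 ± 0.37, adjusted p = 0.00182), Jund (1.18) and Ebf1, a B lineage factor gene (1.51), were higher. Eef1a1 (-1.44 ± 0.26, adjusted p = 8.09e-05), Cd9 (-1.39), Psmb3 (-1.0), Klf2 (-1.0) and RT1-CE16 (-2.29, from 6 UMIs in the I library) were lower. With the sex block Eef1a1 was at -0.85 (0.0167) and Klf2 was lost (0.0883). The haemoglobin genes Hba-a2 and Hbb-b1 were among the 13, lower (log2 -1.37 and -1.80), with haemoglobin at 1888 CPM in I and at 1399 and 11024 CPM in the C F and C M libraries. Ebf1 had log2 -0.13 with doublets kept. All 8 of these calls ended without the C F (0.0678 to 0.563) or the C M (0.167 to 0.728) pancreas library, and all but that of Ebf1 without the I F (0.103 to 0.367) or the I M (0.0994 to 0.339). Crebbp (0.0698), Jund (log2 0.78, 0.252), Cd9 (0.113), Psmb3 (0.244) and Klf2 (0.258) were lost without the C M spleen library, and Klf2 without the C F (0.0858). In B cell precursor-like cells 7 of 1173 genes passed, 4 higher and 3 lower, among them Ube4b (2.10 ± 0.51), Rgl1 (1.29) and Eef1a1 (-1.70 ± 0.28, adjusted p = 4.06e-05). The other lower genes were Hba-a2 (-1.39) and Hbb-b1 (-1.78), with haemoglobin at 1503 CPM in I and at 6732 and 2906 CPM in the C F and C M libraries. The count was 22 with the sex block, 2 in DESeq2, and 20, 25, 15 and 37 without the C M, I F and I M pancreas and C F spleen libraries. Ube4b was lost with the sex block (0.336) and without the C F (0.548) and C M (0.97) spleen libraries and Rgl1 without the C M (0.202). Oxidative phosphorylation was lower there (adjusted p = 0.0039, and 0.298 with an estimated correlation), with 0 of 52 past in either count and Ndufa4 at log2 -0.49. In cluster 10, Hist1h2an, a histone gene, was at 969 against 2285 ± 20.0 CPM (log2 -1.24 ± 0.19, adjusted p = 0.00518), and 4 of 4800 genes passed. Of the others, Mdga2 had 23 of 23 UMIs from 1 cell, Neto2, chosen after its value was seen, had log2 5.39, and 1 has no symbol. Cell cycle genes were lower in cluster 10 (0.00381, 0 of 29 past, 1 adjusted over the list alone, Stmn1 at log2 -0.77). Interferon response genes were higher (0.00504, 0 of 3 past, 1 adjusted over the list alone, Bst2 at log2 1.73). Both lists had adjusted p = 0.802 with an estimated correlation. In cluster 7, 1 of 563 genes passed, which has no symbol. The count was 5 with the sex block, 6, 5 and 12 without the I F and I M pancreas and C F spleen libraries and 0 without the C M spleen library. Jund had log2 1.33 (adjusted p = 0.282), Cdca3 0.72 (0.345), Stmn1 -0.95 (0.182) and Eef1a1 -1.39 (0.282) there, and Jund (0.0302) and Stmn1 (0.00572) passed with the sex block. MHC class I presentation and lymphocyte effector and T helper genes were called in no class of either tissue, though Ccl5 of the latter list was higher in innate lymphoid cell-like cells (list adjusted p = 0.966).

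Between the organs of C animals, cluster 6 was all but limited to the pancreas, with 13.8% ± 4.75 (SD, n = 2) of cells there against 1 of 4773 and 0 of 5718 spleen cells. Dendritic cell-like cells were 28.1-fold, granulocyte precursor-like cells 18.1-fold, innate lymphoid cell-like cells 8.69-fold, neutrophil-like cells 6.0-fold and plasmacytoid dendritic cell-like cells 4.21-fold more frequent in pancreas (edgeR's quasi-likelihood test on cell numbers, Benjamini-Hochberg adjusted p of 0.0012 or smaller). The log2 ratio was -7.92 for cluster 1, -6.17 for erythroid cell-like cells, -3.02 and -2.30 for the proliferating clusters 10 and 7 and -2.17 for B cell precursor-like cells. Without the C F spleen library cluster 7 (0.0508) and B cell precursor-like cells (0.0791) no longer passed. With the stricter cell filter the log2 ratio of plasmacytoid dendritic cell-like cells was -1.07 (0.226) and that of innate lymphoid cell-like cells 0.86 (0.281). Dendritic cell-like cells were at log2 4.81 in the main test and 3.72 with that filter, and clusters 7 and 10 at -5.87 and -5.59 with it. Neutrophil-like cells were at log2 2.59 in the main test, 4.38 with the stricter filter and 4.82 without the gene minimum, which left out most of them in pancreas. Without it 386 and 275 of these cells were counted in the C F and C M pancreas libraries (9.25% and 7.16%), against 61 and 41 with it, and 19 and 11 in the spleen ones (0.390% and 0.191%). Scaling by TMM over the classes gave log2 3.82, 3.26, 2.15, 1.61 and 1.04 for dendritic, granulocyte precursor, innate lymphoid, neutrophil and plasmacytoid dendritic cell-like cells, and the last no longer passed (0.105). Macrophage-like cells made 26.2% ± 0.666 of pancreas and 0.708% ± 0.185 of spleen cells, monocyte-like cells 23.0% ± 5.21 and 2.47% ± 0.534, and B cell-like cells 1.80% ± 0.106 and 34.5% ± 6.02. Genes that lead these 3 classes differed between the tissues, so these shares describe the clusters and are not set against each other as cell types. In all, 15 of 20 classes passed, 9 of them higher in pancreas. NK cell-like cells had log2 -1.08 (adjusted p = 0.0709). The sorted numbers differed by tissue, and a share is relative to the other sorted cells.

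Pancreas monocyte-like and macrophage-like cells held chemokine transcripts that were not seen in those of C spleen. Ccl2 was at 870 ± 19.2 CPM (SD, n = 2) in pancreas monocyte-like cells and at 0 UMIs in spleen, at least 193-fold higher (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.28e-08). Ccl12, Atf3, a stress response factor gene, Mt2A, a metallothionein gene, and Cxcl1 were at least 34.8-fold, 25.8-fold, 21.2-fold and 19.4-fold higher. Samhd1 (log2 -2.81 ± 0.35), Megf9 (-2.76) and the B cell genes Cd79a (-2.66 ± 0.36), Cd79b (-3.04) and Ebf1 (-3.16) were lower. Whether B cell transcripts in the spleen monocyte-like and macrophage-like cells were free RNA was not tested. Without the C M spleen library Ccl12 (0.0987), Mt2A (0.0565), Megf9 (0.125) and Cd79b (log2 -2.02, 0.319) were lost. So were, without the C M pancreas library, Ccl12 (0.0535), Megf9 (0.0687) and Cd79b (0.0635). Of the monocyte-like genes 554 passed, 306 higher and 248 lower (170 in DESeq2). The count was 246, 134, 906, 348 and 117 without the C F, C M and I M pancreas and C F and C M spleen libraries. Most of these cells lie in cluster 2 in C pancreas and in cluster 8 in C spleen. In macrophage-like cells, Ccl2 was at 1383 ± 242 CPM in pancreas and at least 47.2-fold higher, Ccl7 31.9-fold, Ltc4s, a leukotriene synthase gene, 23.4-fold, Colec12 19.6-fold and Cxcl2 16.1-fold, each a lower bound. Ccl2, Ccl12 and Mt2A lead the monocyte-like clusters, and Ccl7, Ltc4s and Colec12 the macrophage-like ones. Cd79a (-6.72 ± 0.29), Ebf1 (-6.74), Ikzf3 (-5.49), Cd79b (-5.05) and Bcl11a (-4.54), genes of B cells and other lymphoid cells, were lower. The spleen cells of this class, 40 and 33 cells, all lie in cluster 18. B cell marker genes summed there to 3140 and 3880 CPM, against 155 and 101 CPM in pancreas. Here 593 genes passed, 347 higher and 246 lower (162 higher among 416 in DESeq2). The count was 272 and 283 without the C F and C M spleen libraries, and the median of all genes lay at log2 0.30.

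B cell-like cells of C pancreas held more S100a9 (741 ± 642 against 69.4 ± 6.01 CPM, SD, n = 2 each; log2 3.40 ± 0.41, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.95e-05) and S100a8 (2.98 ± 0.49), genes of granulocytes and monocytes. They also held more of the endoplasmic reticulum genes Creld2 (2.86 ± 0.48) and Pdia6 (2.36 ± 0.46) and of Oasl2, an interferon-induced gene (2.49 ± 0.56). Neutrophil-like and granulocyte precursor-like cells were more frequent in C pancreas than in C spleen. Whether S100a9 and S100a8 came from free RNA of such cells was not tested. Pax5, a B cell identity factor gene, had 1 UMI in pancreas, a ratio of 0.0851 (counting interval 0.00215 to 0.476), and Sox5 2 UMIs, a ratio of 0.0707 (0.00856 to 0.256). Ctse, Prkce and Vpreb3, a gene of the B cell precursor receptor, were at 0 UMIs in pancreas, at least 3.24-fold, 3.18-fold and 3.63-fold lower. Of these cells, 27 and 11 lie in cluster 0 and 31 and 41 in cluster 4 in the C F and C M pancreas libraries, against 1064 and 1746 in cluster 0 and 381 and 472 in cluster 4 in the spleen ones. Sox5 leads cluster 0 and not cluster 4. S100a9 and S100a8 were lost without the C F pancreas library (log2 1.71, 0.0857, and 1.64, 0.257), as was Pax5 (0.0896). Oasl2 was lost without the C M pancreas (0.378), C F spleen (0.139) and C M spleen (0.183) libraries, and Pdia6 without the C F spleen library (0.0652). Of these genes 165 passed, 54 higher and 111 lower (109 higher among 179 in DESeq2). The count was 108, 274 and 98 without the C M and I M pancreas and C M spleen libraries. In other classes the counts were 194 in haematopoietic progenitor-like cells (85, 108, 127 and 125 without the C F, C M and I M pancreas and C M spleen libraries) and 146 in NK cell-like cells (13, 26 and 82 without the C F and C M pancreas and C M spleen libraries). They were 71 in B cell precursor-like cells (27, 118 and 43 without the C F and I F pancreas and C M spleen libraries) and 30 in cluster 7 (4, 3, 77, 73 and 10 without the C F, C M, I F and I M pancreas and C M spleen libraries).

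The difference of the I effect between pancreas and spleen was tested in 7 classes, each fitted over all libraries and among the classes tested in pancreas or spleen. T cell-like, plasmacytoid dendritic cell-like and cluster 16 cells also reached 20 cells in each library and were not tested for it. In haematopoietic progenitor-like cells, Mcpt9, a mast cell protease gene, was at 939 and 1059 CPM in the C and 1688 and 1356 CPM in the I pancreas libraries, and at 1823 and 1490 CPM in the C and 596 CPM in the I spleen libraries (log2 difference 2.07 ± 0.26 SE, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.71e-07). Mcpt9 also leads the mast cell-like cluster. In this class 3 genes passed, and the count was 6 with the sex block and 24 and 8 without the C F and C M spleen libraries. In macrophage-like cells 12 genes passed, all with a higher effect in pancreas. The count fell to 2 to 7 when any 1 of the pancreas or C spleen libraries was left out (6, 5, 5 and 7 for the C F, C M, I F and I M pancreas and 3 and 2 for the C F and C M spleen libraries). The median of all genes lay at log2 0.50. The named ones, S100a8, S100a9, S100a6, Clec4a3 and Brk1, had 0 or 1 UMI in the 29 macrophage-like cells of the I spleen library. In C spleen, 33 of 37 and 40 of 40 UMIs of S100a8 came from 1 cell in each library. In monocyte-like, B cell-like, NK cell-like, B cell precursor-like and cluster 7 cells, 0 genes passed in edgeR or DESeq2, with 236, 104, 95, 72 and 23 at an unadjusted p under 0.05. With the sex block 3, 0, 2, 2 and 2 genes passed in these classes. In monocyte-like cells 23 genes passed without the I M pancreas library, where Np4 (log2 2.62, adjusted p = 0.985 with all libraries, 0.00712 with the sex block) had log2 3.35 (1.33e-12). Eef1a1 had log2 1.32 in NK cell-like (adjusted p = 0.108) and 1.85 in B cell precursor-like cells (0.0848, and 0.0473 with the sex block).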

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

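The tests of free RNA and of a shift of the whole I spleen library were chosen after the results were seen. The tests of granulocytes inside the classes, of depth and of other splits by sex letter were set before.

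The I effect differed between pancreas and spleen by a test of the difference itself for 12 genes in macrophage-like and 3 genes in haematopoietic progenitor-like cells. In macrophage-like cells the log2 differences were 11.47 for S100a8, 10.19 for Clec4a3, 9.88 for Brk1, 4.97 for S100a9 and 4.17 for S100a6. The I spleen library held 29 cells of this class with 0 or 1 UMI of each of these genes, so the fitted values depend on the prior count and are no bounds. S100a8 was lost without the C F (adjusted p = 0.0748, edgeR) and C M (0.173) spleen libraries, S100a9 without the C M spleen library (0.209), and S100a6 without the C F (0.0539), C M (0.145) and I M (0.751) pancreas and the C F (0.433) and C M (0.698) spleen libraries. Clec4a3 was lost without the C F (0.056), I F (0.106) and I M (0.055) pancreas and the C F (0.096) and C M (0.173) spleen libraries. Brk1 was lost with the sex block (0.0748) and without each library but the I spleen one (0.0788 to 0.345). With the highest cell of each gene left out the count was 2, and none of the 5 named genes passed (0.41 to 0.914). In haematopoietic progenitor-like cells Prg2 had a log2 difference of 12.31, which rests on a few cells of 127 and 413 UMIs in the I pancreas libraries and was lost without the highest cell (0.445), and Mcpt9 one of 2.07, which was past the threshold in each alternative. Both genes lead the mast cell-like cluster, which held 26 and 20 cells in the I and 1 and 5 in the C pancreas libraries.

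Among barcodes under the gene minimum, which the comparisons left out, 40.6% and 22.1% were nearest to neutrophil-like cells in the C F and C M pancreas libraries and 47.6% and 31.6% in the I F and I M pancreas libraries. Without the gene minimum the pancreas shares again had 1 class past the threshold.

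Defensin transcripts (Np4, Defa5 and RatNP-3b) were higher in I than in C pancreas in each of 13 classes other than granulocytes and their precursors. Free RNA from granulocytes would raise all classes by a like ratio. The log2 ratios of I to C spanned a range of 1.24 over the classes, from 1.35 in B cell-like cells to 2.60 in cluster 16. The rule counted against free RNA only ratios whose counting intervals lay apart. These ran from 0.481 to 2.331 in B cell-like cells and from 0.773 to 5.025 in cluster 16 (15 UMIs in I against 3 in C). Unlike ratios could therefore be missed. The granulocyte precursor-like cells hold the source transcripts, and the defensins over all cells were 7135 and 4087 CPM in C and 23955 and 17798 CPM in I. Whole granulocytes as the only source are argued against, since without cells of 3 or more granule UMIs all 13 classes kept over 0.5 of their log2 ratio, with counting intervals above 0 in 11 (not in B cell precursor-like cells and cluster 16). The cells left out held over 0.5 of the defensin UMIs of monocyte-like cells (724 to 215 in I and 161 to 46 in C), of I B cell precursor-like cells (18 to 8), of cluster 17 in I (50 to 24) and of C B cell-like cells (13 to 5), and for UMIs left out in any class granulocytes stay open. Free RNA may account for the rest, and a condition effect on the share of granulocyte precursor-like cells (adjusted p = 0.131, and 0.0473 with the sex block) stays open.

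The same genes recurred across spleen classes of the I library, with Crebbp and Jund higher in 6 of 6 tested classes. Of 90 values of called genes in classes that did not call them, 78 (86.7%) had the called sign, against 61.9% for genes called in no class, each set against its class of smallest p. A shift of the whole library would give at least 90%, so the share decides nothing, and with 1 I spleen library such a shift cannot be told apart from an effect of the condition. Over all cells Crebbp was at 143 and 149 CPM in I and 63.0 and 59.7 CPM in C pancreas, and at 113 CPM in I and 51.6 and 47.9 CPM in C spleen. A condition effect, which may cover both organs for this gene, therefore stays open.

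The B cell-like share of 60.1% in the I spleen library could reflect its lower depth of 606 UMIs per cell. Cluster 1, led by B lineage genes, went the other way, at 12.3% in this library and 14.7% and 25.5% in the C F and C M spleen libraries. So did clusters 7 and 10, each with 7 of 10 B cell markers raised, and B cell precursor-like cells. These were at 3.54%, 2.30% and 2.20% in the I spleen library. They were at 12.3%, 6.39% and 9.83% in the C F and at 5.96%, 5.18% and 4.41% in the C M spleen library. The B cell-like share therefore does not stand for the whole B lineage. Thinned to 300 UMIs per cell, the log2 ratio of B cell-like shares to the C M spleen library was 0.63, against 0.631 before, with 0 cells left out. This argues against an effect of depth on the labels of kept cells. It cannot test which barcodes were called cells, and the lowest held 352 UMIs in the I and 462 and 500 in the C F and C M spleen libraries. An effect of depth on which cells were kept, a condition effect and a difference between single pools stay open.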

How the results depend on the processing

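Alternatives without a gene minimum, with single clusters or without the highest cell of each gene were chosen after the data were seen. Of 2792 values of named genes under an alternative, 2367 kept direction and side of the threshold, 356 lost the call, 57 gained it and 12 changed sign. These include list members and genes named as not passing, which had no call to lose. The part that kept its side is therefore no measure of how often a call held. For lists 254 of 388 kept and 134 lost the call, for shares 226 of 240 kept direction and side, and of 409 counts 217 stayed within 1.5 times.

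The numbers of genes past the threshold follow. In pancreas, with all libraries, they were 2 in monocyte-like, 34 in macrophage-like, 23 in cluster 6, 6 in dendritic, 3 in innate lymphoid and 1 in progenitor-like cells, and in spleen 6 in B cell-like, 20 in cluster 1, 1 in cluster 7, 13 in NK, 7 in B precursor-like cells and 4 in cluster 10. Between tissues they were 554 in monocyte, 593 in macrophage, 194 in progenitor, 165 in B cell, 146 in NK, 71 in B precursor-like cells and 30 in cluster 7. For the difference of the I effect they were 12 in macrophage, 3 in progenitor-like and 0 in the other classes.

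Without the filter on low counts they were 17 in monocyte and 28 in progenitor-like cells of pancreas, 41 in B cell-like cells, 9 in cluster 1, 0 in cluster 7, 16 in B precursor-like cells and 18 in cluster 10 of spleen, 0 in cluster 7 and 173 in B precursor-like cells between tissues, and for the difference 4 in monocyte, 5 in macrophage, 10 in progenitor, 2 in B cell, 2 in NK and 1 in B precursor-like cells. With the sex block they were 20, 22, 0 and 5 in monocyte, macrophage, innate lymphoid and progenitor-like cells of pancreas, 5, 25 and 22 in cluster 7, NK and B precursor-like cells of spleen, and for the difference 3, 6, 2, 2 and 2 in monocyte, progenitor, cluster 7, NK and B precursor-like cells. With the libraries of 1 tissue they were 0 and 14 in monocyte and macrophage-like cells of pancreas and 95, 18 and 4 in B cell-like, cluster 7 and B precursor-like cells of spleen. With DESeq2 they were 0, 4, 6, 1 and 0 in monocyte, macrophage, cluster 6, dendritic and innate lymphoid-like cells of pancreas, 1, 0 and 2 in cluster 1, NK and B precursor-like cells of spleen, 170, 99 and 78 in monocyte, progenitor and NK-like cells between tissues, and 1 for the difference in macrophage-like cells. The stricter cell filter gave 1 in pancreas monocyte-like cells, 17 in spleen cluster 10 and 354 between monocyte-like cells of the tissues. Doublets kept gave 3 and 0 in cluster 6 and innate lymphoid-like cells of pancreas, 0, 3 and 19 in cluster 1, B precursor-like cells and cluster 10 of spleen and 7 for the difference in macrophage-like cells. No gene minimum gave 5 in pancreas monocyte-like cells and 1 for their difference. Without the highest cell of each gene they were 6, 3 and 0 in monocyte, cluster 6 and innate lymphoid-like cells of pancreas, 1 and 27 in B precursor-like cells and cluster 10 of spleen, 43 in B precursor-like cells between tissues and 2 for the difference in macrophage-like cells. Alone, cluster 2 gave 6 and cluster 8 gave 12 in pancreas monocyte-like cells and cluster 8 gave 6 for their difference. Cluster 18 alone gave 0 in pancreas macrophage-like cells, 85 between tissues and 0 for the difference, cluster 0 alone 42 in spleen B cell-like cells, and cluster 4 alone 78 between tissues.

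Leaving out 1 library in turn gave these ranges. In pancreas they were 0 to 75 for monocyte, 13 to 20 for macrophage, 8 to 43 for cluster 6, 1 to 12 for dendritic, 0 to 2 for innate lymphoid and 1 to 6 for progenitor-like cells. In spleen they were 0 to 49 for B cell-like, 0 to 12 for cluster 7, 0 to 28 for NK and 7 to 37 for B precursor-like cells. Between tissues they were 117 to 906 for monocyte, 272 to 559 for macrophage, 85 to 193 for progenitor, 98 to 274 for B cell, 3 to 77 for cluster 7, 13 to 143 for NK and 27 to 118 for B precursor-like cells. For the difference they were 0 to 23 for monocyte, 2 to 7 for macrophage, 2 to 24 for progenitor, 0 to 4 for B cell, 0 to 2 for cluster 7, 0 to 3 for NK and 0 to 7 for B precursor-like cells. Genes that follow the sex letter numbered 15 with all libraries, 119 without the filter, 9 with DESeq2 and 5 to 227 with 1 library left out.

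Lists called in pancreas numbered 21, and 0 with an estimated correlation, 0 with fry, 11 with the pancreas libraries alone, 6 with the stricter filter and 13 to 20 with 1 library left out. In spleen they numbered 8, and 0 with an estimated correlation, 1 with fry, 3 with the sex block, 4 without the highest cells, 1 with the stricter filter and 2 to 10 with 1 library left out. Of the class shares 1 passed in pancreas, 0 with the stricter filter or at either other clustering resolution and 0 to 1 with 1 library left out, and 15 between tissues, 9 at resolution 0.5 and 13 to 17 with 1 library left out.

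These values changed sign. Il4r in pancreas macrophage-like cells was at log2 -0.066 with the sex block, -0.033 with DESeq2, and -0.167 and -0.795 without the C F and I M pancreas libraries, within a range of -0.795 to 0.397 over libraries left out. Without the I M library RT1-Ba was at 0.099 in macrophage-like (range -0.896 to 0.099) and Tsc22d3 at 0.133 in dendritic cell-like cells (-0.166 to 0.133), and Tsc22d3 at 0.031 without a gene minimum. Cd74 was at 1.17 in cluster 6 without the C F library (-1.65 to 1.17) and at 0.021 in cluster 8 alone, Ebf1 at -0.13 in spleen NK-like cells with doublets kept, Eef1a1 at -0.148 for the difference in NK-like cells without the I F library (-0.148 to 2.15), Pkm at 0.083 in cluster 0 of spleen alone, and the share of plasmacytoid dendritic cell-like cells at -1.07 with the stricter filter. For all of these the cause was not tested. The sex letter, which pairs an F and an M library across the groups, was the block, since the replicate numbers follow the order of deposit. Leaving out a library or blocking on sex left no residual degrees of freedom in the spleen fits of clusters 1 and 10, and the stricter filter was not run where a class fell under 20 cells. Depth limits the spleen macrophage-like class (29 to 40 cells) and genes under 10 UMIs in a library.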

Other observations

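The test of the count of genes by sex letter was planned before, the choice of distinct splits was made after the counts were seen, and the gene levels in this part were chosen after the data were seen.

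The levels over all kept cells of some genes called within classes follow. Jund, a gene of the AP-1 factor, was at 1498 and 1399 CPM in the I and 980 and 1041 CPM in the C pancreas libraries, and at 333 CPM in the I and 198 and 120 CPM in the C spleen libraries. RT1-CE16, an MHC class I gene, was at 188 and 178 CPM in I and 301 and 249 CPM in C pancreas, and at 55.8 CPM in I and 136 and 152 CPM in C spleen. Eef1a1, an elongation factor gene, was at 1005 and 284 CPM in the I F and I M and 844 and 478 CPM in the C F and C M pancreas libraries, and the sex letter did not pass for it (log2 1.07 in F over M, edgeR's quasi-likelihood test, adjusted p = 0.0657). In spleen Eef1a1 was at 399 CPM in the I M and 1315 and 976 CPM in the C F and C M libraries.

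The share of cells with a haemoglobin UMI was higher in both I than in both C pancreas libraries in 13 of 13 classes. In macrophage-like cells it was 16.2% and 9.11% in the I F and I M and 2.53% and 3.23% in the C F and C M libraries (median 781 to 889 UMIs), and in cluster 6 it was 11.8% and 4.23% against 1.56% and 2.08%. Dendritic cell-like cells were at 24.6% and 20.8% against 13.9% and 8.72%, and NK cell-like cells, which should lack these transcripts, at 8.40% and 7.36% against 1.5% and 0.99% (median 534 to 664 UMIs). Among the macrophage-like cells of the I libraries, 737 of 847 and 680 of 1257 haemoglobin UMIs came from 1 cell, and without it the levels were 420 and 971 CPM. Endocrine marker genes, which islet cells make, were at 2659.6 and 181 CPM in the C F and C M and 14.4 and 1257.5 CPM in the I F and I M libraries over all cells.

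With the group as a term, the lone I spleen library carries no weight and mirrored splits are the same fit, which leaves 4 distinct splits that part the libraries of each of the other 3 groups. These are too few for a share under 0.05. The sex letter gave 15 genes and the highest other split 15, and 2 of the 4 reached that count, the real one included. Of the 35 splits into 3 and 4 libraries that were planned, 3 could not be fitted with the group as a term, and of the other 32, 6 reached it and the highest other gave 35. These are 3 distinct fits, those 2 and the sex letter with both C pancreas libraries on one side.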
